A study of Mus musculus with 30 samples.

How the data were processed

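RNA was sequenced from 14 libraries of mouse ES cells and EBs. Of these, 10 came from E14Tg2a.IV cells, 2 on each of 5 days (0 to 4), and 4 from EBs at day 4, 2 from a Trp53+/+ line and 2 from a Trp53-/- line with short hairpin RNAs against p63 and p73. Per the labels, libraries were made with TruSeq RNA v2 from RNA with an integrity number over 9.5 and sequenced with paired ends. The authors name FastQC 0.11.3, Bowtie2, SAMtools 0.1.19, HTSeq 0.5.4, DESeq2 and the mouse build mm9, without the role or order of each. The 16 ChIP-seq and input samples of the series were not analysed here. The labels do not say whether the 2 libraries of a group are separate cultures, so p-values measure the spread between these samples only.

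The deposited tables, 1 for the time course and 1 for the genotypes, give for 23284 genes, named by symbol and without positions, a signal that is the read count divided by 1 factor per library. This was tested on the files: 100% of the values in each library were whole multiples of its smallest step within 1e-06, and dividing by that step gave whole reads. In the time course the factors equalled median-of-ratios size factors computed from the recovered reads, with a ratio of 1. In the genotype table the ratio was 0.921 to 0.941, nearly the same for its 4 libraries, so values of the 2 tables are not set side by side as levels except in CPM. Recovered reads came to 20104644 to 39835808 per time course library and 19104692 to 31580252 per genotype library. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules, and the floor is 3 reads per library where a group had none.

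The test of each comparison was limma 3.58.1 (R 4.3.3), with an intensity trend in its empirical Bayes step, on log2 of the deposited signal plus a pseudocount of 1, and Benjamini-Hochberg adjusted p under 0.05. The design first set edgeR's quasi-likelihood test with TMM on counts. It was changed to limma when the files turned out to hold scaled counts, and edgeR on the recovered reads became an alternative. Genes were filtered with edgeR's filterByExpr on the recovered reads, which left 15841 genes in the time course and 14840 in the genotype table. Each table was fitted as a whole, with 5 residual degrees of freedom (and 4.98 prior ones) in the time course and 2 (and 4.33 prior ones) in the genotype table. The comparisons were day 4 with day 0, each day with the day before, any change over the 5 days, and p53 family loss with Trp53+/+. Tested on simulated data, the time course fit for day 4 and day 0 recovered 22.4% of 2-fold, 73.1% of 4-fold and 78.8% of 8-fold changes, and the genotype fit 43.3%, 89.6% and 89.4%. Only 67, 67 and 66 genes were changed by these folds, far fewer than were called between day 0 and day 4 in the data.

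The comparisons, the rule for named genes, 27 gene lists and all but the later added alternatives were fixed before the data were examined, and the lists cover the p53 family and its targets, pluripotency, streak, mesoderm, endoderm, neural and other cell types, Wnt, Nodal and BMP signalling, Hox genes, stress, hypoxia, proliferation and sex-linked genes. Lists with at least 3 tested members, 26 of them, were compared with all other genes by camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at a correlation estimated from the residuals as an alternative. The estimated form also rests on the residual degrees of freedom alone, 5 in the time course and 2 in the genotype table. It therefore has little power, least in the genotype table. A second alternative, fry, asks whether the genes of a list move on balance one way against no change, and does not compare them with other genes. The rule names the 6 largest rises and 6 largest falls of day 4 against day 0 and of the genotypes (3 for the steps) among called genes whose groups do not overlap and whose higher group has a mean of at least 10 CPM, leaving out Gm, Rik and LOC symbols. It adds up to 4 members of each list with the smallest p (2 for the steps), and always Trp53, Trp63, Trp73, Wnt3, Fzd1, T, Eomes, Mixl1, Mesp1, Gsc, Foxa2, Sox17, Lefty2, Axin2, Pou5f1, Nanog, Zfp42, Sox1, Cdkn1a and Mdm2. Members outside this rule that are named (Krt8 of day 0, and genes of the closing section) were chosen after their values were seen. Foxf1, Usp17lc and Map2 appear in the tables as Foxf1a, Usp17l5 and Mtap2.

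Genes called with a log2 fold change over 1 between day 0 and day 4 formed the induced list, those under -1 the lowered list, and changing genes with a range over 1 were also grouped by the day of their highest mean. These lists were tested with camera in the genotype comparison, and their overlap with its calls with Fisher's exact test, two-sided, over the 14691 genes tested in both tables. Each genotype library was correlated (Spearman) with the mean of each E14 day over the genes changing on any day.

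The alternatives were DESeq2 1.42.0, edgeR 4.0.16 with TMM or with size factors, limma on TMM or size-factor scaling, no filter on low counts, at least 5 CPM in 2 libraries, pseudocounts of 0.5 and 8, the replicate number as a block, only the 4 libraries of the 2 days, both ES day 0 libraries left out, each library left out in turn, other list tests, other fold limits and Pearson's correlation for the closest day. A group left with 1 library is assumed to vary like the other groups.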

Results

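RNA was sequenced from mouse embryonic stem (ES) cells and from the embryoid bodies (EBs) that they form when they differentiate in suspension. The study asks how p53, a stress-responsive transcription factor, acts together with Wnt and TGF-β signals on the genes of mesendoderm, the precursor of mesoderm and endoderm. Of the 14 libraries, 10 came from the E14Tg2a.IV line (129/Ola), called E14 here, with 2 libraries on each of 5 days from ES cells at day 0 to EBs at day 4. The other 4 came from EBs at day 4, 2 from a Trp53+/+ line and 2 from a Trp53-/- line that carries short hairpin RNAs against p63 and p73, called p53 family loss here. The E14 libraries held 20104644 to 39835808 reads each, and the 4 libraries of the genotype comparison 19104692 to 31580252. Across genes, which are not independent replicates, Spearman's correlation between the 2 libraries of a group was 0.962 at day 0 and 0.984 to 0.995 in the other groups. Means are normalised read counts ± SD over n = 2 libraries, and log2 fold changes are given ± SE.

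The comparison of day 4 with day 0 asked which genes change as E14 cells leave the ES cell state. Genes of the primitive streak, the site where mesoderm and endoderm form in the embryo, rose together. T (Brachyury), a T-box factor of nascent mesoderm, rose from 77.3 ± 30.4 to 18956 ± 3548, a log2 fold change of 7.96 ± 0.40. Eomes, another T-box factor of the streak, rose from 284 ± 197 to 14831 ± 573. The homeobox gene Mixl1 rose from 17.2 ± 4.18 to 6383 ± 388. Mesp1, which marks the first cardiac and cranial mesoderm, rose from 4.02 ± 1.03 to 2839 ± 542. Of 24 tested streak and mesendoderm genes, 21 rose and 2 fell (21 higher and 2 lower adjusted over the list alone). Streak and mesendoderm genes had a median of 5.59 (adjusted p = 6.3e-14, adjusted p = 0.084 with an estimated correlation). Of 26 tested mesoderm genes, 23 rose (23 higher adjusted over the list alone). Mesoderm genes had a median of 4.80 (adjusted p = 9.0e-15, adjusted p = 0.084 with an estimated correlation). Among them, the rises included Pdgfra (log2 fold change 7.32), Kdr (6.36) and Rspo3 (9.53). Of 12 tested definitive endoderm genes, 11 rose (11 higher adjusted over the list alone). Definitive endoderm genes had a median of 5.59 (adjusted p = 2.7e-09, adjusted p = 0.11 with an estimated correlation). Sox17, an early endoderm regulator, rose from 15.1 ± 9.65 to 1282 ± 91.0, and Foxa2 from 20.8 ± 9.22 to 1211 ± 120.4. The largest log2 rises under the rule for named genes were those of Aplnr (11.72), Lhx1 (10.91), Prdm6 (9.73), Cer1 (9.67), Rspo3 and Mesp1 (9.15).

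The naive pluripotency genes, which hold ES cells in their undifferentiated state, fell over the same 4 days. Zfp42 (Rex1) fell from 21231 ± 508 to 441 ± 98.9, Esrrb from 22885 ± 5829 to 422 ± 140.2 and Nr0b1 from 6609 ± 2669 to 31.6 ± 1.49. Of 21 tested naive pluripotency genes, 20 fell (20 lower adjusted over the list alone). Naive pluripotency genes had a median of -4.50 (adjusted p = 1.0e-16, adjusted p = 0.095 with an estimated correlation). Pou5f1 (Oct4) fell from 44184 ± 2178 to 17180.5 ± 2926, and Nanog from 1518 ± 290.0 to 449 ± 9.01. Of 10 tested general pluripotency genes, 6 fell (7 lower adjusted over the list alone). General pluripotency genes had a median of -1.11 (adjusted p = 8.5e-04, adjusted p = 0.21 with an estimated correlation). Primed epiblast genes, which mark the state that follows naive pluripotency, went both ways. Fgf5 rose from 154 ± 156 to 3993 ± 757, while Dnmt3l fell from 11541 ± 8630.4 to 934 ± 51.4. Of 11 tested primed epiblast genes, 6 rose and 3 fell (6 higher and 3 lower adjusted over the list alone). Primed epiblast genes had a median of 1.19 (adjusted p = 0.16). Of 11 tested germ cell genes, 8 fell (9 lower adjusted over the list alone). Germ cell genes had a median of -2.68 (adjusted p = 6.1e-05, adjusted p = 0.084 with an estimated correlation). The two-cell-like state is a rare ES cell state with transcripts of the early embryo. Of 8 tested two-cell-like genes, 8 fell (8 lower adjusted over the list alone). Two-cell-like genes had a median of -2.27 (adjusted p = 4.6e-04, adjusted p = 0.28 with an estimated correlation). The other largest log2 falls were those of Tcl1 (-6.89), Jam2 (-6.69), Myo1f (-6.60), Krt42 (-6.49) and Inhbb (-6.19).

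Many Wnt genes and targets of Wnt, Nodal and BMP signals rose with the streak genes. The Wnt ligand, Wnt target, Nodal/Activin, mesoderm and definitive endoderm lists share members with the streak list. Wnt3, the ligand that starts the streak in the embryo, rose from 124 ± 74.6 to 2618 ± 124. The Wnt receptor gene Fzd1 rose from 72.7 ± 11.3 to 804 ± 154, and Axin2, a direct target of β-catenin, from 911 ± 3.49 to 4399.6 ± 1241. Of 17 tested Wnt ligand genes, 10 rose and 2 fell (10 higher and 2 lower adjusted over the list alone). Wnt ligand genes had a median of 3.25 (adjusted p = 0.0014, adjusted p = 0.18 with an estimated correlation). Wnt2 had no read at day 0 and was at least 52.4-fold higher at day 4 against a floor of 3 reads per library. Of 15 tested Wnt receptor genes, 9 rose and 1 fell (10 higher and 1 lower adjusted over the list alone). Wnt receptor genes had a median of 1.15 (adjusted p = 0.0014, adjusted p = 0.36 with an estimated correlation). Of 20 tested Wnt target genes, 14 rose and 1 fell (14 higher and 1 lower adjusted over the list alone). Wnt target genes had a median of 2.12 (adjusted p = 9.2e-06, adjusted p = 0.095 with an estimated correlation). Of 18 tested Nodal/Activin target genes, 10 rose and 3 fell (10 higher and 3 lower adjusted over the list alone). Nodal/Activin target genes had a median of 1.71 (adjusted p = 0.0010, adjusted p = 0.084 with an estimated correlation). Fst, an Activin-binding protein, rose from 107 ± 47.9 to 7225 ± 203. Lefty2, an inhibitor and target of Nodal, had a log2 fold change of -0.05 ± 0.53 (adjusted p = 0.95). Of 12 tested BMP target genes, 6 rose and 2 fell (6 higher and 2 lower adjusted over the list alone). BMP target genes had a median of 1.10 (adjusted p = 0.013, adjusted p = 0.40 with an estimated correlation). Msx1, one of them, rose from 14.1 ± 4.86 to 1405 ± 782. Of 16 tested Hox genes, 11 rose (12 higher adjusted over the list alone). Hox genes had a median of 2.66 (adjusted p = 5.9e-05, adjusted p = 0.28 with an estimated correlation).

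Trp53 itself fell from 14140.2 ± 1569.7 to 8845 ± 1087, and Trp73 from 523 ± 323 to 168 ± 10.8. They were the 2 tested members of the p53 family (2 lower adjusted over the list alone). Trp63, with means of 2.20 and 4.76, was not tested. Of 32 tested p53 target genes, 3 rose and 10 fell (3 higher and 11 lower adjusted over the list alone). The p53 target genes had a median of -0.55 (adjusted p = 0.010, adjusted p = 0.50 with an estimated correlation). Ephx1 was at -2.76 on the log2 scale, Gdf15 at -3.04 and Sesn2 at -1.32. Mdm2, the ubiquitin ligase that restrains p53, fell from 7517 ± 4574 to 3212 ± 455. Cdkn1a (p21) had 5597 ± 6118 at day 0 and 2607 ± 653 at day 4 (adjusted p = 0.63). The 2 day 0 libraries differed in p53 target and stress genes, with Cdkn1a at 9923 and Fos at 5860 in replicate 1 against 1272 and 144 in replicate 2. Of 14 tested immediate early and stress genes, 6 fell (6 lower adjusted over the list alone). Immediate early and stress genes had a median of -1.52 (adjusted p = 0.0051, adjusted p = 0.32 with an estimated correlation).

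Genes of several other lists rose, some of them already counted above. The cardiac list shares Isl1, Hand1, Hand2, Mef2c and Tbx20 with the mesoderm list. The hematopoietic and endothelial list shares Kdr with it, and the visceral and parietal endoderm list shares Gata4 and Gata6 with the definitive endoderm list. Of 15 tested cardiac genes, 8 rose and 1 fell (8 higher and 1 lower adjusted over the list alone). Cardiac genes had a median of 2.05 (adjusted p = 0.0068, adjusted p = 0.11 with an estimated correlation). Hand1, a factor of heart and extraembryonic mesoderm, rose from 33.2 ± 3.45 to 5709 ± 5039.8. Of 16 tested hematopoietic and endothelial genes, 8 rose and 3 fell (11 higher and 3 lower adjusted over the list alone). Hematopoietic and endothelial genes had a median of 2.20 (adjusted p = 0.0014, adjusted p = 0.11 with an estimated correlation). Of 20 tested visceral and parietal endoderm genes, 10 rose (12 higher adjusted over the list alone). Visceral and parietal endoderm genes had a median of 1.11 (adjusted p = 9.1e-04, adjusted p = 0.28 with an estimated correlation). Of 15 tested hypoxia and glycolysis genes, 9 rose (9 higher adjusted over the list alone). Hypoxia and glycolysis genes had a median of 1.02 (adjusted p = 8.8e-04, adjusted p = 0.32 with an estimated correlation). Of 16 tested proliferation genes, 5 fell (5 lower adjusted over the list alone). Proliferation genes had a median of -0.41 (adjusted p = 0.0069, adjusted p = 0.28 with an estimated correlation). Camera called no shift against other genes for the primed epiblast list or for the following 5. Of 19 tested neuroectoderm genes, 5 rose and 4 fell (5 higher and 4 lower adjusted over the list alone). Neuroectoderm genes had a median of 0.14 and a mean of -0.24 (adjusted p = 0.90). Of 9 tested trophoblast genes, 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone). Trophoblast genes had a median of 0.23 (adjusted p = 0.21). Of 12 tested feeder fibroblast genes, 2 rose and 2 fell (2 higher and 2 lower adjusted over the list alone). Feeder fibroblast genes had a median of -0.06 and a mean of 0.09 (adjusted p = 0.93). Of 16 tested epithelial-mesenchymal transition genes, 5 rose and 2 fell (5 higher and 2 lower adjusted over the list alone). Epithelial-mesenchymal transition genes had a median of 0.37 (adjusted p = 0.092). Snai1, a driver of that transition, rose from 233 ± 143 to 3235 ± 487. Sex-linked genes had a median of -0.46 (adjusted p = 0.36).

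Over the 15841 tested genes limma called 3045 higher and 2653 lower at day 4, of which 2390 and 1699 differed by more than 2-fold, and 6159 genes changed on any day (10525 without ES day 0 replicate 2, 3570 without EB day 4 replicate 1 and 3444 without replicate 2). Without EB day 4 replicate 1 or replicate 2 the counts were 1553 and 1264 or 1490 and 1339, and the falls of Trp53 (without EB day 4 replicate 1), of Trp73 (without either day 4 library) and of Mdm2 (without either, or without ES day 0 replicate 1) were no longer called. Without ES day 0 replicate 1, Cdkn1a and Lefty2 were called higher at day 4, with log2 fold changes of 1.01 and 0.99, and without replicate 2 lower, with -1.95 and -1.10.

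**Figure D1:**
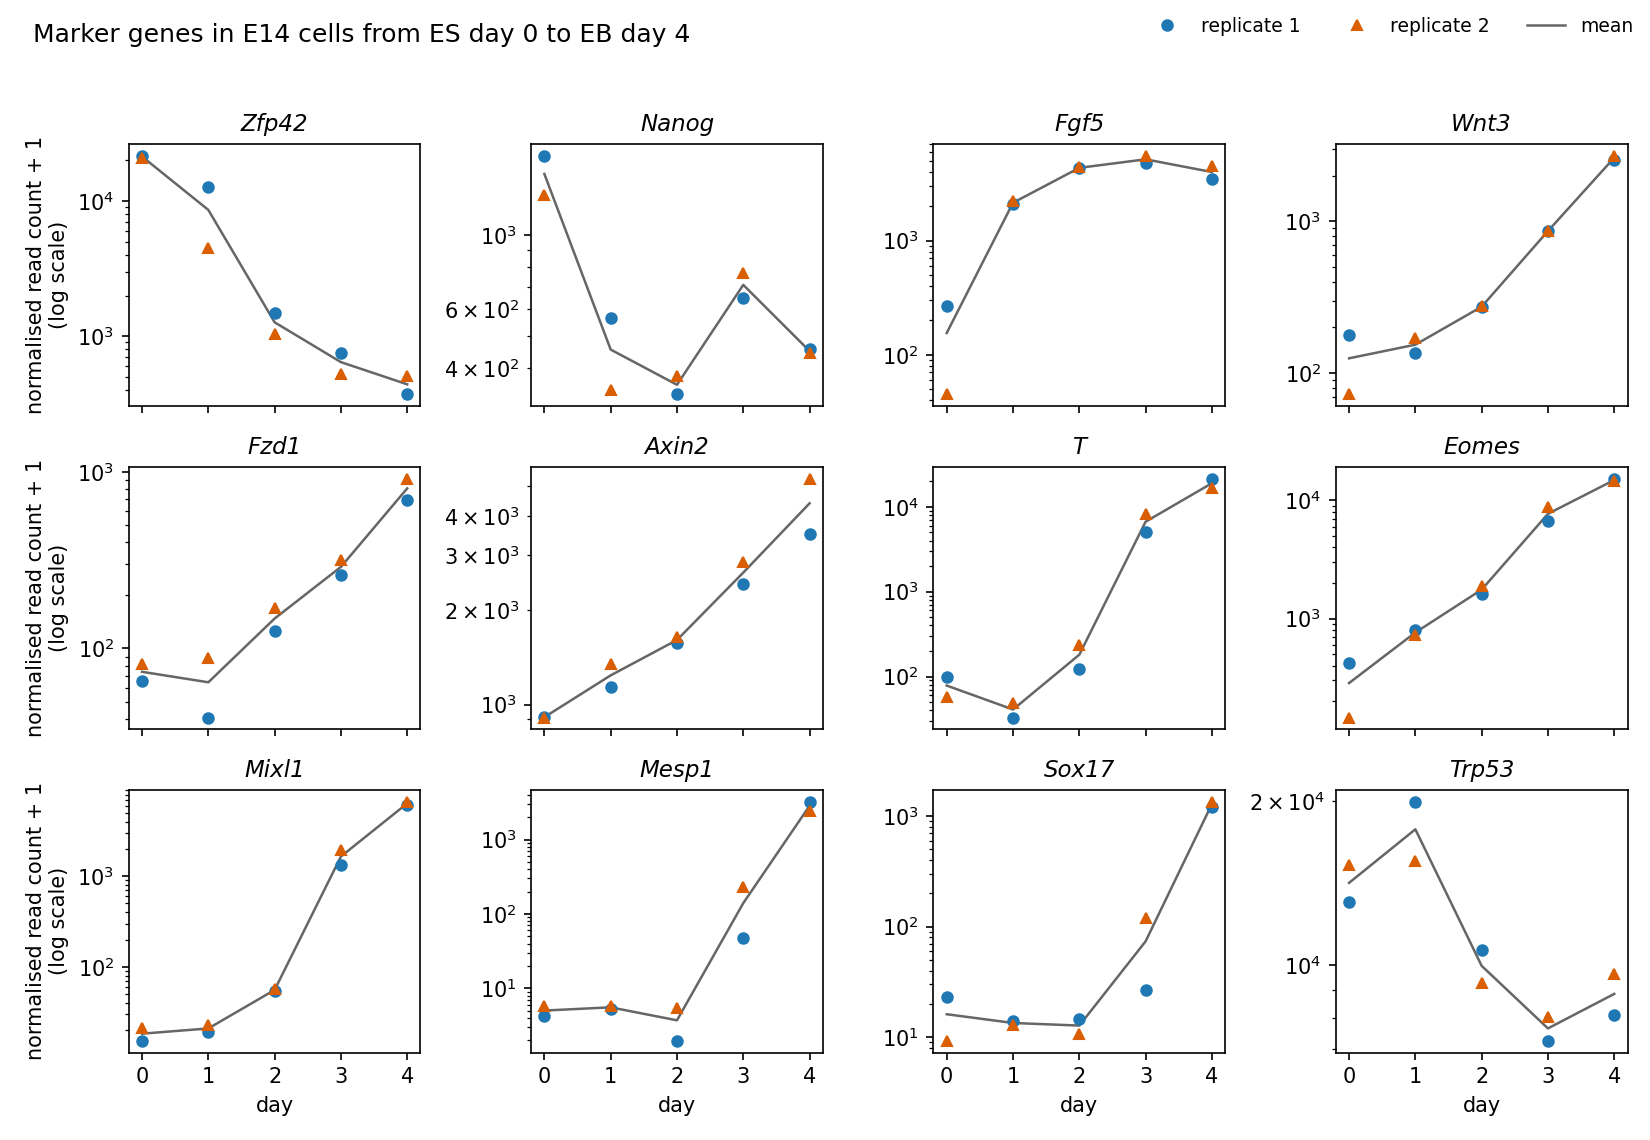
Normalised read count plus 1, on a log scale, against day for 12 genes in the E14 libraries, with circles for replicate 1, triangles for replicate 2 and a line through the mean of the 2 libraries. Mean counts of T went from 77.3 at day 0 to 18956 at day 4, and those of Zfp42 from 21231 to 441.

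The steps between neighbouring days asked when these changes took place. From day 0 to day 1, primed epiblast genes rose and part of the naive network fell. Otx2, a homeobox gene of the primed epiblast, rose from 1198 ± 25.4 to 6195 ± 784, Fgf5 from 154 ± 156 to 2147 ± 103 and Sall2 from 558 ± 143 to 5015 ± 439.8. Of 11 tested primed epiblast genes, 7 rose (9 higher adjusted over the list alone). Primed epiblast genes had a median of 2.24 (adjusted p = 2.9e-12, adjusted p = 0.17 with an estimated correlation). Klf4 fell from 8494 ± 1916 to 764 ± 466, and Tfcp2l1 from 12156 ± 1943 to 2859 ± 614. Of 21 tested naive pluripotency genes, 6 fell (9 lower adjusted over the list alone). Naive pluripotency genes had a median of -0.96 (adjusted p = 1.1e-06, adjusted p = 0.51 with an estimated correlation). Socs3, a feedback inhibitor in the LIF pathway, fell from 5323 ± 420.0 to 195 ± 6.39. The early streak ligand Wnt8a rose from 90.5 ± 55.0 to 1006 ± 421, whereas Sp5, a Wnt target, fell from 874 ± 616 to 37.7 ± 0.906. Of 14 tested immediate early and stress genes, 3 fell (8 lower adjusted over the list alone). Immediate early and stress genes had a median of -1.39 (adjusted p = 2.4e-06, adjusted p = 0.48 with an estimated correlation). Their median was 1.43 higher in day 0 replicate 1 than in replicate 2, and their mean change of -1.73 was -1.02 without replicate 1 and -2.45 without replicate 2. Of 9 tested trophoblast genes, 4 fell (4 lower adjusted over the list alone). Trophoblast genes had a median of -0.94 (adjusted p = 0.0020, adjusted p = 0.51 with an estimated correlation). The keratin Krt8 of that list was at 13918 in day 0 replicate 1 and 4261 in replicate 2.

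From day 1 to day 2 the naive network fell further. Zfp42 fell from 8568 ± 5797 to 1267 ± 324, and Tcl1 from 889.6 ± 319 to 96.1 ± 31.6. Of 21 tested naive pluripotency genes, 8 fell (18 lower adjusted over the list alone). Naive pluripotency genes had a median of -1.46 (adjusted p = 1.8e-17, adjusted p = 0.44 with an estimated correlation). Prdm14, a regulator of naive and germ cells, fell from 483 ± 293 to 43.0 ± 19.4. Notum, a secreted Wnt inhibitor and target, fell from 1449 ± 847 to 122 ± 33.3. Fst rose from 339 ± 15.9 to 1504 ± 265. T had a mean of 39.9 at day 1 and 179.9 at day 2 (adjusted p = 0.055).

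From day 2 to day 3 streak genes rose. T rose from 179.9 ± 80.0 to 6672 ± 2316, and Mixl1 from 54.4 ± 2.23 to 1652 ± 435. Foxa2 rose from 106 ± 8.61 to 1075 ± 76.5, and Mesp1 from 2.71 ± 2.45 to 139 ± 131. Of 24 tested streak and mesendoderm genes, 8 rose (15 higher adjusted over the list alone). Streak and mesendoderm genes had a median of 1.88 (adjusted p = 9.8e-24, adjusted p = 0.065 with an estimated correlation). Of 18 tested Nodal/Activin target genes, 5 rose (7 higher and 1 lower adjusted over the list alone). Nodal/Activin target genes had a median of 0.14 (adjusted p = 4.5e-05, adjusted p = 0.065 with an estimated correlation). Lhx1 rose from 9.74 ± 1.31 to 764 ± 639, and the Nodal and Wnt antagonist Cer1 from 0.934 ± 0.0635 to 255 ± 269.9. Eomes had a mean of 1756 at day 2 and 7682 at day 3 (adjusted p = 0.099). Wnt3 had 272 and 860.2 (adjusted p = 0.17). Hox genes had a median of -1.34, 5 of 16 being lower adjusted over the list alone (adjusted p = 3.8e-06, adjusted p = 0.28 with an estimated correlation).

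From day 3 to day 4 genes of mesoderm and its subtypes rose. Kdr, the VEGF receptor of blood and vessel precursors, rose from 239.6 ± 42.2 to 8849.9 ± 496, and Pdgfra from 183 ± 58.8 to 3729.6 ± 28.6. Of 26 tested mesoderm genes, 21 rose (23 higher adjusted over the list alone). Mesoderm genes had a median of 3.31 (adjusted p = 6.1e-35, adjusted p = 0.015 with an estimated correlation). The paraxial mesoderm regulator Msgn1 rose from 2.41 ± 0.711 to 838 ± 76.6. Of 24 tested streak and mesendoderm genes, 13 rose (18 higher adjusted over the list alone). Streak and mesendoderm genes had a median of 2.24 (adjusted p = 7.2e-16, adjusted p = 0.046 with an estimated correlation). Hand2 had no read at day 3 and was at least 125-fold higher at day 4 against the same floor, and Hand1 rose from 25.5 ± 5.09 to 5709 ± 5039.8. Of 15 tested cardiac genes, 6 rose (11 higher adjusted over the list alone). Isl1, Hand1, Hand2, Mef2c and Tbx20 of this list are also in the mesoderm list. Cardiac genes had a median of 1.99 (adjusted p = 2.5e-12, adjusted p = 0.015 with an estimated correlation). Of 16 tested hematopoietic and endothelial genes, 6 rose (7 higher adjusted over the list alone). Hematopoietic and endothelial genes had a median of 1.19 (adjusted p = 3.9e-07, adjusted p = 0.046 with an estimated correlation). Wnt5a rose from 53.8 ± 24.8 to 2279 ± 549, and Wnt3 from 860.2 ± 2.75 to 2618 ± 124. Of 17 tested Wnt ligand genes, 6 rose (8 higher adjusted over the list alone). Wnt ligand genes had a median of 1.28 (adjusted p = 7.8e-09, adjusted p = 0.046 with an estimated correlation). Of 20 tested Wnt target genes, 5 rose (11 higher adjusted over the list alone). Wnt target genes had a median of 1.03 (adjusted p = 2.2e-08, adjusted p = 0.046 with an estimated correlation). Of 12 tested BMP target genes, 8 rose (9 higher adjusted over the list alone). BMP target genes had a median of 2.10 (adjusted p = 7.8e-13, adjusted p = 0.069 with an estimated correlation). Sox17 rose from 72.6 ± 66.2 to 1282 ± 91.0, while Pou5f1 fell from 33039 ± 5501 to 17180.5 ± 2926.

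Camera called 9, 5, 17 and 20 of the 26 tested lists over the 4 steps, in order, and 6 of them, all from day 3 to day 4, with an estimated correlation. The counts of genes called higher and lower by limma were 277 and 246 from day 0 to day 1, 25 and 69 from day 1 to day 2, 21 and 0 from day 2 to day 3 and 366 and 98 from day 3 to day 4. For the 0 genes lower from day 2 to day 3, 918 had an unadjusted p under 0.05, DESeq2 called 142, and edgeR called 0 with either of its scalings. From day 0 to day 1 the counts without 1 library were 2675 and 2501 without ES day 0 replicate 2, 119 and 108 without EB day 1 replicate 1, 27 and 40 without EB day 1 replicate 2. They were 118 to 162 higher and 111 to 152 lower without any 1 library of days 2 to 4. From day 1 to day 2 they were 923 and 805 without ES day 0 replicate 1, 938 and 801 without ES day 0 replicate 2 and 488 and 318 without EB day 1 replicate 2. Without EB day 1 replicate 1 or any 1 library of days 2 to 4 limma called 0, where with all libraries 1696 and 1357 genes had an unadjusted p under 0.05 and DESeq2 called 658 and 642. From day 2 to day 3, 112 and 104 or 114 and 103 were called without ES day 0 replicate 1 or 2. The genes higher were 11 without either day 1 library, 2 or 3 without a day 2 library, 1 (Mixl1) without EB day 3 replicate 2, and 3 or 7 without a day 4 library. From day 3 to day 4, 817 and 509 or 830 and 501 were called without ES day 0 replicate 1 or 2, and 25 lower without either day 2 library. The counts were 56 and 2 without EB day 3 replicate 1, 209 and 29 without EB day 3 replicate 2, 103 and 13 without EB day 4 replicate 1, and 42 and 1 without EB day 4 replicate 2. With both day 0 libraries left out, a setting added after the data were seen, the last 3 steps gave 956 and 792, 117 and 95, and 807 and 506.

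The comparison of the 2 lines at day 4 asked which genes differ between p53 family loss and Trp53+/+ in differentiating EBs. With 1 line per genotype, loss of the p53 family cannot be told apart from other differences between the lines. From Trp53+/+ to p53 family loss, Trp53 fell from 10061 ± 2436 to 834 ± 45.1, and Trp73 from 258 ± 55.3 to 50.3 ± 3.13 (2 lower adjusted over the list alone). Trp63, at 5.69 and 2.22, was not tested, so its loss is not shown. Known targets of p53 fell with it. Cdkn1a, the cell cycle inhibitor p21, fell from 2209.7 ± 160.3 to 165 ± 53.2, and Ccng1 from 5502 ± 813 to 291 ± 16.1. Phlda3 fell from 1639 ± 408 to 41.6 ± 5.58, and the death receptor gene Eda2r from 766 ± 94.1 to 25.6 ± 2.74. Of 32 tested p53 target genes, 9 fell (1 higher and 26 lower adjusted over the list alone). The p53 target genes had a median of -1.02 (adjusted p = 5.2e-23, adjusted p = 0.095 with an estimated correlation). Mdm2 was 2707 ± 474 in Trp53+/+ and 1673 ± 131 in p53 family loss (adjusted p = 0.16).

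Mesendoderm genes were lower in p53 family loss. T fell from 9692 ± 849 to 1327 ± 321, a log2 fold change of -2.89 ± 0.20. Mesp1 fell from 1032 ± 426 to 94.4 ± 25.8, a log2 fold change of -3.40 ± 0.35. Eomes fell from 14382 ± 3338 to 3291 ± 252, Mixl1 from 4729.5 ± 786 to 836 ± 1.19 and Evx1 from 1787 ± 142 to 318 ± 10.4. Of 24 tested streak and mesendoderm genes, 13 fell (22 lower adjusted over the list alone). Streak and mesendoderm genes had a median of -2.10 (adjusted p = 4.0e-31, adjusted p = 0.095 with an estimated correlation). Of 25 tested mesoderm genes, 4 fell (14 lower adjusted over the list alone). Mesoderm genes had a median of -1.28 (adjusted p = 5.4e-10, adjusted p = 0.28 with an estimated correlation). The 4 lower mesoderm genes were Mesp1, Snai1 (-2.10), Msx1 (-2.71) and Rspo3 (-2.07). Mesp1 and Snai1 are also in the streak list, so the mesoderm list is only partly separate from it. Of 12 tested definitive endoderm genes, 2 fell (1 higher and 8 lower adjusted over the list alone). Definitive endoderm genes had a median of -1.54 (adjusted p = 1.2e-07, adjusted p = 0.35 with an estimated correlation). The 2 lower endoderm genes were Foxa2, which fell from 2139 ± 259 to 697 ± 41.8, and Gsc, which fell from 1575 ± 124 to 421 ± 170.4. Both are also in the streak list. Sox17 was 1010.0 ± 619.7 in Trp53+/+ and 236 ± 82.6 in p53 family loss (adjusted p = 0.12).

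Some genes of the Wnt and Nodal pathways were lower, and many of these are streak genes already counted above. Wnt3, Wnt3a, T, Sp5, Mixl1, Eomes, Lhx1, Foxa2 and Gsc are also in the streak list, so these lists are no separate evidence. Wnt3 fell from 1199 ± 129 to 239 ± 27.3, and Fzd1 from 885 ± 129 to 230.1 ± 15.3. Of 16 tested Wnt ligand genes, 1 rose and 4 fell (3 higher and 8 lower adjusted over the list alone). Wnt ligand genes had a median of -1.25 (adjusted p = 4.2e-04, adjusted p = 0.29 with an estimated correlation). Wnt3a (-3.09) and Wnt5b (-2.30) were among those lower. Wnt1 had no read in the Trp53+/+ libraries and was at least 5.40-fold higher in p53 family loss against the floor of 3 reads per library. Of 19 tested Wnt target genes, 2 fell (6 lower adjusted over the list alone). Wnt target genes had a median of -0.63 (adjusted p = 7.2e-07, adjusted p = 0.29 with an estimated correlation). The 2 lower Wnt target genes were T and Sp5, which fell from 5008 ± 919.7 to 893 ± 0.0426, whereas Axin2 was 2491 ± 119 in Trp53+/+ and 1283 ± 171 in p53 family loss (adjusted p = 0.064). Of 15 tested Wnt receptor genes, 1 fell (1 higher and 2 lower adjusted over the list alone). Wnt receptor genes had a median of 0.21 (adjusted p = 0.41). Of 18 tested Nodal/Activin target genes, 7 fell (9 lower adjusted over the list alone). Nodal/Activin target genes had a median of -0.80 (adjusted p = 2.7e-07, adjusted p = 0.24 with an estimated correlation). Lhx1, one of them, fell from 6124 ± 2203 to 1043 ± 184. Lefty2 was 1574 ± 659.7 in Trp53+/+ and 2201 ± 464 in p53 family loss (adjusted p = 0.55). Of 12 tested BMP target genes, 1 fell (1 lower adjusted over the list alone). BMP target genes had a median of -0.03 (adjusted p = 0.36). Msx1, also in the mesoderm list, was the lower BMP target.

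Neuroectoderm genes were higher in p53 family loss. Sox1, the earliest marker of the neural plate, rose from 114 ± 14.5 to 2740.3 ± 204, a log2 fold change of 4.57 ± 0.19. The eye and forebrain factor Pax6 rose from 17.3 ± 0.0907 to 483 ± 18.6, a log2 fold change of 4.72 ± 0.27. Lhx2 rose from 18.2 ± 6.12 to 219 ± 8.05, and Pax3 from 6.36 ± 0.390 to 74.0 ± 29.2. Of 17 tested neuroectoderm genes, 4 rose (11 higher adjusted over the list alone). Neuroectoderm genes had a median of 1.79 (adjusted p = 2.0e-12, adjusted p = 0.24 with an estimated correlation). Of 16 tested epithelial-mesenchymal transition genes, 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone). Epithelial-mesenchymal transition genes had a median of -0.20 (adjusted p = 0.26). Zeb1 (2.24) was the higher and Snai1 the lower of these genes. Of 18 tested hematopoietic and endothelial genes, 2 rose (7 higher and 2 lower adjusted over the list alone). Hematopoietic and endothelial genes had a median of 0.55 (adjusted p = 0.0039, adjusted p = 0.49 with an estimated correlation). The 2 higher ones were the embryonic globin Hba-x, which rose from 3.75 ± 4.08 to 101 ± 10.3, and Sox18, which rose from 30.5 ± 0.0758 to 132 ± 23.0. Of 13 tested feeder fibroblast genes, 2 rose (3 higher adjusted over the list alone). Feeder fibroblast genes had a median of 0.52 (adjusted p = 4.2e-04, adjusted p = 0.28 with an estimated correlation). Acta2 rose from 279 ± 50.3 to 926 ± 4.89, and Col1a2 from 207 ± 75.5 to 1062 ± 276.

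Naive pluripotency genes showed no shift by camera. Their median was -0.08 over 21 genes (0 adjusted over the list alone, adjusted p = 0.41). Zfp42 was 609 ± 134 in Trp53+/+ and 631 ± 92.7 in p53 family loss (adjusted p = 0.94). Of 10 tested general pluripotency genes, 1 fell (1 higher and 3 lower adjusted over the list alone). General pluripotency genes had a median of -0.19 (adjusted p = 0.036, adjusted p = 0.47 with an estimated correlation). The lower gene was Tdgf1, a co-receptor of Nodal, which fell from 18473 ± 1781 to 7189 ± 324. Of 11 tested primed epiblast genes, 1 rose (2 higher and 1 lower adjusted over the list alone). Primed epiblast genes had a median of -0.03 and a mean of 0.08 (adjusted p = 0.73). The higher gene was Sall2, which rose from 3708 ± 176 to 7638 ± 348. Two-cell-like genes had a median of 2.93, 6 of 8 being higher adjusted over the list alone (adjusted p = 3.0e-06, adjusted p = 0.39 with an estimated correlation). Germ cell genes had a median of 0.66, 4 of 11 being higher adjusted over the list alone (adjusted p = 0.015, adjusted p = 0.68 with an estimated correlation). No two-cell-like or germ cell gene passed over all genes, Zscan4d being 4.14 ± 3.98 in Trp53+/+ and 76.6 ± 24.4 in p53 family loss (adjusted p = 0.052). In 7 further lists neither a member nor the list passed. Their medians were 0.08 for cardiac genes (1 higher adjusted over the list alone, adjusted p = 0.73), -0.04 for visceral and parietal endoderm genes (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.51) and -0.04 for trophoblast genes (0 adjusted over the list alone, adjusted p = 0.49). Further medians were -0.30 for Hox genes (1 lower adjusted over the list alone, adjusted p = 0.65) and -0.05 for proliferation genes (0 adjusted over the list alone, adjusted p = 0.33). For the last pair they were 0.03 for hypoxia and glycolysis genes (0 adjusted over the list alone, adjusted p = 0.77) and 0.12 for immediate early and stress genes (2 higher adjusted over the list alone, adjusted p = 0.19). The direction of the hypoxia list changed with the library left out.

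The lines also differed at Y-linked genes and at single other genes. The Y-linked genes Eif2s3y and Uty had no read in the Trp53+/+ libraries. They were at least 184-fold and 136-fold higher in p53 family loss against the floor of 3 reads per library. Ddx3y rose from 0.434 ± 0.614 to 475 ± 38.6, and Kdm5d from 0.663 ± 0.938 to 156 ± 85.1. With these, 4 of the 5 tested sex-linked genes were higher (4 higher adjusted over the list alone, adjusted p = 1.0e-08, adjusted p = 0.28 with an estimated correlation). The imprinted growth regulator Grb10 fell from 11465 ± 573 to 387 ± 18.96. Mid1 rose from 439 ± 63.6 to 7965 ± 1567, and Gbp1 fell from 253 ± 74.6 to 0.430 ± 0.608. Rn45s, the ribosomal RNA precursor, took 0.632% (95% Wilson interval 0.629 to 0.635) and 4.30% (4.29 to 4.31) of the reads in Trp53+/+ replicates 1 and 2. In p53 family loss it took 0.848% (0.845 to 0.851) and 2.91% (2.91 to 2.92). Within libraries of number 1 and of number 2, the log2 fold changes were -3.27 and -3.87 for Trp53, -2.73 and -3.05 for T, -2.32 and -2.66 for Mixl1 and 4.78 and 4.37 for Sox1.

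Over the 14840 tested genes limma called 84 higher and 100 lower in p53 family loss, all of them by more than 2-fold. The differences between replicates correlated at 0.57 across genes between the 2 lines, though the labels do not say that replicate numbers pair the samples. With the replicate number as a block 1548 and 1425 were called, so genes that did not pass in the main fit are not shown to be unchanged. DESeq2 called 289 and 377, the filter at 5 CPM left 41 and 65, and the counts were 979 and 634 without Trp53+/+ replicate 1 and 519 and 594 without Trp53+/+ replicate 2, where the lone library was assumed to vary like the other groups. Sall2 lost its call without either library of p53 family loss, Sox18 and Pax3 without its replicate 1, Gsc with the filter at 5 CPM, and Wnt1 with edgeR, with a pseudocount of 8 and without either library of p53 family loss.

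**Figure D2:**
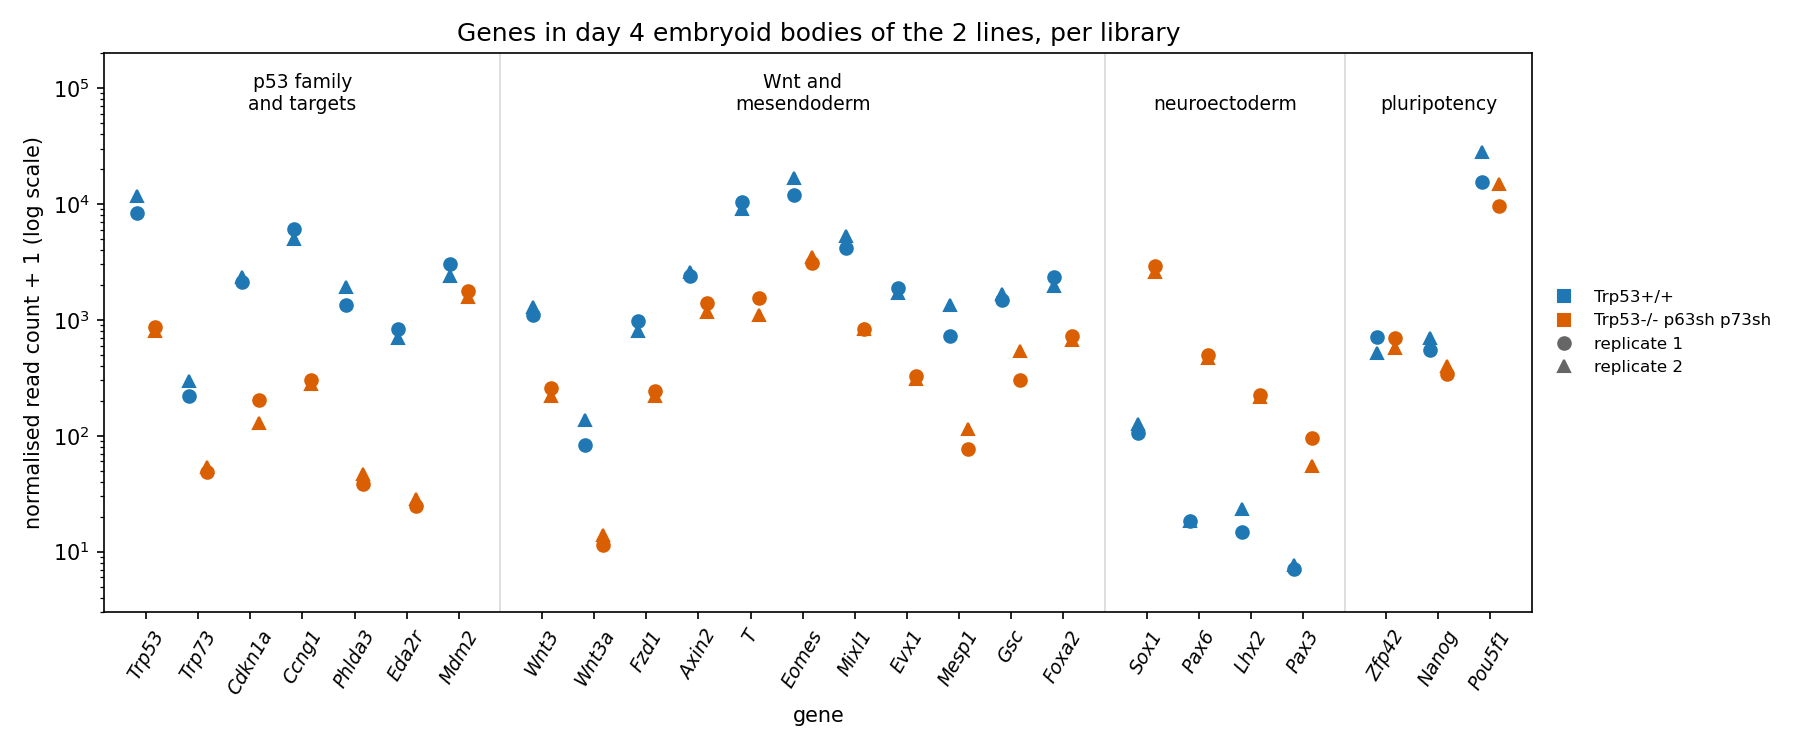
Normalised read count plus 1, on a log scale, of 25 genes in the 4 libraries of day 4 EBs, with Trp53+/+ in blue, p53 family loss in orange, circles for replicate 1 and triangles for replicate 2. Both libraries of p53 family loss lay below both Trp53+/+ libraries for T (means 1327 and 9692) and above them for Sox1 (2740.3 and 114).

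**Figure D3:**
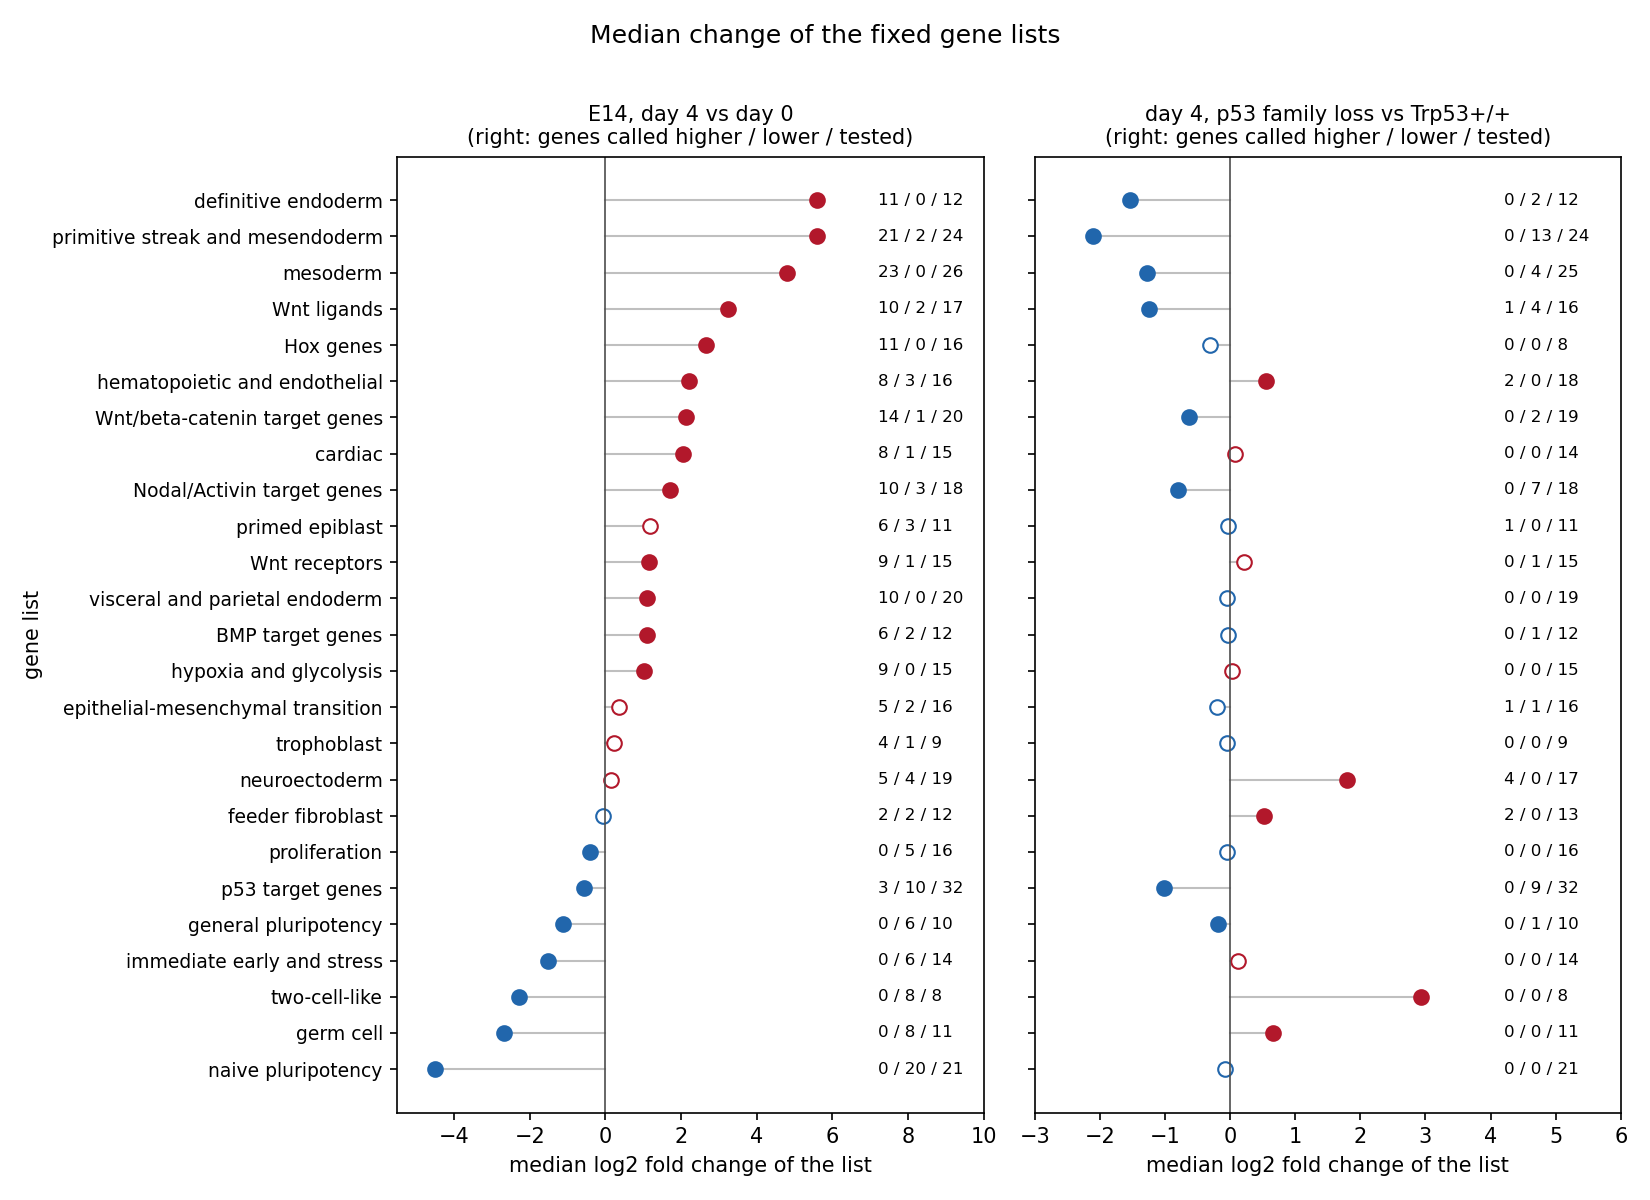
Median log2 fold change of the fixed lists in E14 from day 0 to day 4 (left) and between the lines at day 4 (right). The sex-linked and p53 family lists are not drawn. Filled circles mark an adjusted p under 0.05 by camera at the preset correlation, and open circles the rest. The genes called higher, called lower and tested stand at the right. The streak list had a median of 5.59 in E14 and -2.10 in p53 family loss, and the neuroectoderm list 0.14 and 1.79.

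A last comparison asked whether the genes that E14 cells switch on by day 4 are those lower in p53 family loss. Of the 100 genes lower in p53 family loss, 47 were genes induced more than 2-fold by day 4 in E14, where 15.4 would be shared by chance. The odds ratio was 4.94 by Fisher's exact test, two-sided (95% interval 3.25 to 7.48, adjusted p = 3.3e-13). Genes are not independent of each other, so the Fisher tests here describe the lists only. Over all 14691 genes tested in both tables, the log2 fold changes of day 4 against day 0 and of p53 family loss correlated at -0.088 (Spearman). Of the 74 higher genes tested in both tables, 24 were genes lowered by day 4 in E14, against 6.98 by chance (odds ratio 4.67, 95% interval 2.74 to 7.77, Fisher's exact test, adjusted p = 6.9e-08). The opposite overlaps were 15 induced genes among the higher ones, against 11.4 by chance (Fisher's exact test, adjusted p = 0.34), and 9 lowered genes among the lower ones, against 9.43 (adjusted p = 1, Fisher's exact test). The induced list had a mean log2 fold change in p53 family loss of -0.14 over 2268 genes (adjusted p = 0.0050, adjusted p = 0.26 with an estimated correlation). For the lowered list it was 0.25 over 1386 genes (adjusted p = 0.0031, adjusted p = 0.26 with an estimated correlation). Genes highest at day 0 in E14 had a mean of 0.17 over 1059 genes (adjusted p = 0.059). Those highest at day 1 had 0.26 over 736 genes (adjusted p = 0.0016, adjusted p = 0.45 with an estimated correlation), and at day 2 0.26 over 491 genes (adjusted p = 7.1e-04, adjusted p = 0.45 with an estimated correlation). For day 4 it was -0.22 over 1812 genes (adjusted p = 1.2e-04, adjusted p = 0.45 with an estimated correlation). For day 3 it was -0.01 over 621 genes (adjusted p = 0.75), the median being 0.01.

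Across the 6159 genes that changed in E14, the day whose mean a library matched best by Spearman's correlation was day 4 for Trp53+/+ replicate 1 (0.974, against 0.955 for day 3). For Trp53+/+ replicate 2 days 3 and 4 tied at 0.964. For p53 family loss it was day 3 in both, with 0.951 against 0.948 for day 4 in replicate 1 and 0.962 against 0.945 in replicate 2. The overlap of induced and lower genes was 204 (96.7 by chance) without Trp53+/+ replicate 1, 276 (91.2) without Trp53+/+ replicate 2, 81 (21.0) without p53 family loss replicate 1 and 174 (55.2) by DESeq2. Observed over expected was 2.11, 3.03, 3.86 and 3.15 in these, against 3.04 with all libraries. Shifts that were no longer called were those of the induced genes without Trp53+/+ replicate 1 (-0.05) or ES day 0 replicate 2 (-0.09), of the lowered genes without ES day 0 replicate 2 (0.12), and of the genes highest at day 1 without EB day 1 replicate 2 (0.16), at day 2 without Trp53+/+ replicate 1 (0.14) or p53 family loss replicate 2 (0.15) and at day 4 without Trp53+/+ replicate 1 (-0.07). The genes highest at day 3 were called without EB day 3 replicate 2 (-0.16), and those highest at day 0 without Trp53+/+ replicate 1 (0.30), ES day 0 replicate 1 (0.26), p53 family loss replicate 2 (0.23), EB day 1 replicate 2, EB day 4 replicate 2 (both 0.21), EB day 3 replicate 2 or either day 2 library (all 0.19). The best day moved to 4 for Trp53+/+ replicate 2 without replicate 2 of ES day 0, EB day 3 or EB day 4, and for p53 family loss replicate 1 without EB day 3 replicate 2.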

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

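The settings with edgeR and TMM, the TMM and size-factor scalings in limma, the pseudocounts of 0.5 and 8 and the fit without both ES day 0 libraries were chosen only after the data were seen, and the others were planned. Of 245 calls on named genes, 151 held in every setting run and 94 were lost in at least 1, with 91 of 106 kept for day 4 against day 0 and 36 of 41 for p53 family loss, but 10 of 38, 0 of 13, 1 of 10 and 13 of 37 for the 4 steps in order. Where neither fit passed the threshold, 104 values changed direction, 24 for named genes, 74 for gene lists and 6 for E14 gene sets, a list's direction being camera's, against all other genes. DESeq2 gave no adjusted p for 3 named values. Of the other results, gene lists and named genes included, 10640 values kept direction and side of the threshold, 590 passed it in an alternative alone, 591 were lost there and 5 reversed. Of the values that answer a comparison, 344 stayed, 126 moved, 17 were lost and 10 newly passed. No scaling moved the median of all genes by over 0.1. With edgeR and TMM p53 family loss had 84 higher and 100 lower genes, of which 82 and 99 were also called by limma on the deposited values. The cause of the differences below was not tested, except where a fit held fewer libraries.

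With only the 4 libraries of the 2 days, which leaves fewer samples to estimate the spread, the genes higher and lower were 1579 and 1243 for day 4 against day 0, 6 and 18 for day 1 against day 0, 126 and 295 for day 2 against day 1, 136 and 129 for day 3 against day 2, and 1013 and 584 for day 4 against day 3. DESeq2 gave 668 and 779, 658 and 642, 175 and 142, and 669 and 352 for the 4 steps, 289 and 377 for p53 family loss, and 174 genes for the overlap of induced and lower genes. Without a filter on low counts, day 2 against day 1 had 5 and 16 genes and day 3 against day 2 had 1 lower gene, as it had with a pseudocount of 0.5 (1). With at least 5 CPM in 2 libraries, 240 genes were higher at day 4 than at day 3, and p53 family loss had 41 higher and 65 lower. Without both ES day 0 libraries, the last 3 steps gave 956 and 792, 117 and 95, and 807 and 506, and these contained all 25 and 69, all 21, and all 366 and 98 genes called with every library. The replicate numbers were checked as a block although the labels do not say that they pair the samples: across genes, the difference between replicates correlated at -0.19 to 0.35 between days and at 0.57 between the 2 lines. With that block, 3 genes were lower at day 3 than at day 2, p53 family loss had 1548 higher and 1425 lower genes, and the mean of genes highest at day 0 (0.17) passed (adjusted p = 0.046).

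With an estimated correlation 0 of the 20 lists called for day 4 against day 0 by camera were called, 6 of the 51 for the steps, and 0 of the 14 for p53 family loss. As that form has only 5 residual degrees of freedom in the time course and 2 in the genotype table, a call lost there does not show that a list did not move. Tested by fry against no change, 19 lists passed for the steps and 6 for p53 family loss. Induced genes (-0.14) and lowered genes (0.25) lost their call in p53 family loss with an estimated correlation (adjusted p = 0.26 for both). So did the genes highest at day 1 (0.26, adjusted p = 0.45), day 2 (0.26, adjusted p = 0.45) and day 4 (-0.22, adjusted p = 0.45). By fry, which asks another question, these sets did not pass against no change (adjusted p = 0.21 for induced and lowered genes, 0.31 for day 1 and 0.33 for days 2 and 4). Over genes with a range above 2 the closest day became 4 for Trp53+/+ replicate 2 and for p53 family loss replicate 1.

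Leaving out 1 library at a time gave 1490 to 3907 higher and 1264 to 3712 lower genes for day 4 against day 0, 27 to 2675 and 40 to 2501 for day 1 against day 0, 0 to 938 and 0 to 805 for day 2 against day 1, 1 to 114 and 0 to 104 for day 3 against day 2, and 42 to 830 and 1 to 509 for day 4 against day 3. For p53 family loss the ranges were 72 to 979 and 121 to 634, and 3444 to 10525 genes changed on any day. The mean of the induced genes in p53 family loss lay between -0.26 and -0.050, that of the lowered genes between 0.12 and 0.39, and those of genes highest at days 0 to 4 between 0.035 (next lowest 0.068) and 0.30, 0.16 and 0.40, 0.14 and 0.35, -0.16 and 0.072 (with a change of sign, -0.010 being the highest below 0), and -0.37 and -0.071. The overlap ranged from 44 to 276, and the closest day from 3 to 4 for Trp53+/+ replicate 2 and for p53 family loss replicate 1. Both the Cdkn1a change from day 0 to day 4 (-1.95 without ES day 0 replicate 2, adjusted p = 3.4e-04, and 1.01 without replicate 1, adjusted p = 0.013) and that of Lefty2 (-1.10, adjusted p = 0.010, and 0.99, adjusted p = 0.019) reversed with the day 0 library left out. The p53 target list from day 0 to day 1 went from -0.76 (adjusted p = 1.1e-05) to 0.30 (adjusted p = 1.4e-04) in the same way. The hypoxia list in p53 family loss was at -0.36 without its replicate 2 (adjusted p = 0.014), at -0.34 without Trp53+/+ replicate 1 (adjusted p = 0.0062), at 0.39 without p53 family loss replicate 1 (adjusted p = 0.0091) and at 0.37 without Trp53+/+ replicate 2 (adjusted p = 0.0075).

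At this depth and number of libraries small changes were often missed: on simulated data 2-fold changes were recovered in 22.4% of genes for day 4 against day 0, 17.9% for day 3 against day 2 and 43.3% for p53 family loss, against 78.8%, 95.5% and 89.4% at 8-fold, with 7 or 8 unchanged genes called.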

Other observations

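The test of X-linked genes was chosen before its result was seen, and the other tests of this part, with the lists of neural patterning factors and imprinted genes, were chosen only after some results were seen. Some transcription factors that divide the early nervous system into regions were higher in p53 family loss than in Trp53+/+ EBs at day 4. Of 32 tested neural patterning factors, a list picked once neuroectoderm genes were seen to be higher, so that its p is no independent test, 11 were higher (18 higher and 3 lower adjusted over the list alone), with a median log2 fold change of 2.13 (camera adjusted p = 2.6e-10, adjusted p = 0.083 with an estimated correlation). They included factors of forebrain and eye (Six6, from 2.86 ± 1.59 to 176 ± 11.5 normalised counts, and Fezf2, from 10.5 ± 0.13 to 166 ± 18.7, n = 2) as well as of the midbrain and hindbrain border (Gbx2, from 111 ± 15.7 to 654 ± 18.3, and En1, from 26.9 ± 2.45 to 293 ± 184). Gbx2 in the loss libraries (28.6 and 25.8 CPM) lay within the E14 range (3.72 to 90.2). En1 did so in replicate 2 (6.54 CPM, against at most 9.32 in E14) but not in replicate 1 (18.1). Six6 (6.75 CPM or more, against at most 0.298) and Fezf2 (6.16 or more, against at most 1.13) lay above every E14 library.

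Imprinted genes, which are read from 1 parental copy, differed between the lines one by one. Grb10 fell from 11465 ± 573 to 387 ± 18.96 in p53 family loss, while H19 rose from 1935 ± 714 to 6850.1 ± 653, Peg12 from 97.7 ± 46.2 to 589 ± 179 and Sgce from 361 ± 9.83 to 869 ± 28.4 (n = 2). These were the 4 calls among 48 tested genes (8 higher and 4 lower adjusted over the list alone), and the list as a whole showed no shift by camera, with a median log2 fold change of 0.17 (adjusted p = 0.31).

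Y-linked genes were read in both p53 family loss libraries, with at least 111 reads of Kdm5d in each, and gave at most 1 read per gene in the Trp53+/+ libraries. E14 cells mixed into the loss libraries are argued against as the only source of these reads. Kdm5d in CPM was 19.6 times as high in the lower loss library as in the highest E14 library, where it had 6 reads. Some E14 cells in a line with Y-linked reads of its own were not excluded. Against E14 day 4 means, loss replicates 1 and 2 would need 51.1% and 42.8% of E14 for Ddx3y, and 55.7% and 48.05% for Uty. For Eif2s3y they would need 30.5% and 16.8%, and for Trp53 12.4% and 10.8%. A pair of active X chromosomes in the Trp53+/+ line is argued against as well, since the median log2 fold change of 60 X-linked genes (Pgk1 and Amot also being in other lists) differed from that of all genes by -0.029 (SE 0.048), where it was set to lie below -0.3. What stays open is that the 2 lines may differ in sex or origin, or that the Trp53+/+ line may have lost its Y chromosome, and with 1 line per genotype this is confounded with the loss of p53, so that Grb10, Mid1 or Gbp1 could differ for either reason.

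Replicate 1 of ES day 0 stood apart from replicate 2 in p53 target genes, with 29 of 32 higher and Phlda3 at 9881 against 1536, and no biological explanation from the design was tested, as the labels give both libraries the same group. Scaling is argued against, since the median log2 difference of these genes exceeded that of all genes by 0.82, as far as 0% of 2000 random lists. A stress response remains open: the immediate early and stress list lay 1.41 above all genes (11 of 14 members, Fosb at 2307 against 29.7 and Egr1 at 10970.2 against 1627), although its stress genes Chac1 (129.5 against 1839), Trib3 (916 against 2321) and Ddit3 (263 against 334) were lower. Differentiated cells also remain open, as the trophoblast list was 1.04 above all genes (6 of 9 members, 0.65% of random lists as far, the highest of 9 such lists), with Krt8 at 13918 against 4261 and Krt18 at 13732 against 4072, while feeder genes were 0.68 above (2.55%). Of the 9 trophoblast genes, 2 are also in other lists and 5 were above 100 counts in replicate 2, so these transcripts may equally be raised in the ES cells themselves, and against a more differentiated library primed epiblast genes were lower, at -0.75 relative to all genes (2 of 11 higher, 0.5% of random lists), and naive genes 0.36 higher (15 of 21, 3.15%).

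Mesendoderm genes were lower and neuroectoderm genes higher in p53 family loss, and more undifferentiated cells, slower progress along the E14 course and a shift toward neural cells were weighed. More ES cells with the E14 day 0 profile are argued against as the whole cause. The median fall of the streak list would need them to make up 76.7% of the loss EBs. The 17 naive pluripotency genes with a day 0 level over 2 times that of Trp53+/+ EBs allowed at most 2.93% in the median and 19.5% at the highest (Dppa2). A smaller share of ES cells was not excluded. Undifferentiated cells past the naive state were not covered, as the day 0 profile was used and many naive transcripts had fallen in E14 by day 2, before most streak genes rose. Not all had: Fgf4 and Gdf3 had means of 3788 and 1164 normalised counts at day 2, and 886 and 431 at day 3. Slower progress as a cause for part of the neural genes is argued against, since 10 of 17 neuroectoderm genes lay above every E14 library in both loss libraries, against 4 in both Trp53+/+ libraries, with Sox1 at 104 CPM or more against at most 10.6 in E14 and the others from 1.87 (Hesx1) to 16.4 (Irx3), but it stays open for Pax6 (18.9 CPM in the lower loss library, against 41.5 at the highest in E14, at day 0), Sox21 (16.6 against 52.4) and Tubb3 (55.3 against 142), which lay within the E14 range. For genes that fell from day 3 to day 4 in E14, slower progress and its absence cannot be told apart: their mean was 0.27, with 61 of 93 higher (camera p = 0.0079), but p = 0.36 with an estimated correlation, genes that rose in that step had -0.53 (107 of 333 higher, camera p = 7.5e-12, p = 0.32 with an estimated correlation), as slower progress would give, and general pluripotency genes -0.31 (2 of 10 higher, camera p = 0.020, p = 0.22 with an estimated correlation), which goes against it. The p-values with an estimated correlation rest on 2 residual degrees of freedom here, so they cannot decide for or against slower progress. A shift toward neural cells in the absence of the p53 family is left as a hypothesis that was not tested, since with 1 line per genotype no comparison here separates it from the difference between the lines.

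EB day 1 replicate 2 correlated across genes at 0.988 with EB day 2 replicate 1 and at 0.985 with EB day 1 replicate 1 (Spearman), and ES day 0 replicate 2 at 0.980 and 0.976 with the 2 EB day 1 libraries and at 0.962 with ES day 0 replicate 1.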
